A study of Homo sapiens with 6 samples.

How the data were processed

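Polyadenylated RNA from 6 subcutaneous 22Rv1 xenografts was sequenced in paired ends, per the labels' protocols. The deposited table holds raw counts per gene, with 1 column per library and no pooling. Per the submitters' processing notes, the authors used Trimmomatic 0.36, STAR 2.5.2b and featureCounts from Subread 1.5.2, with genome build GRCh38. The annotation release, the strand setting and the treatment of reads that align to several places are not given in the sources used here. Genes that share sequence with close relatives (the kallikrein, CEACAM, HLA, MAGEA and alpha globin genes, and ribosomal proteins with their pseudogenes) can therefore have gained or lost reads. Counts of genes with an overlapping partner on the opposite strand, such as IDH1, MAT2A, CDK4, VIM, PEG10, SYP and CDKN2A, can include reads of the partner. Alignment to the human genome alone would also assign some host reads to human genes, and no host alignment is recorded in the sources used here.

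The table had 32763 rows. There were 13 rows that repeated an identifier and 195 that repeated a symbol with identical counts, and these were collapsed, which left 32555 genes, of which 8474 had 0 counts in all libraries. The table held 0 mitochondrial genes. Positions, gene types, transcript length and GC content came from GENCODE release 29 on GRCh38, to which 31662 identifiers matched. Groups and replicate numbers were taken from the sample labels. Library totals ranged from 11278823 to 15883900 counts. A chi-square statistic per degree of freedom was 3.05 between control replicates 1 and 2 and 2.94 to 3.46 between knockout libraries, above sampling noise. It was 56.9 and 61.8 between control replicate 3 and the other controls. All 6 libraries were counted as samples. Repeat libraries of 1 tumor could also lie above sampling noise, so the statistic does not show that each library came from a separate tumor.

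Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with its minimum count of 10, libraries were scaled by TMM factors (0.88 in control replicate 3, 0.99 to 1.06 in the others), and the quasi-likelihood test compared the groups with no further covariate. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. CPM values use TMM-scaled library sizes. Gene lists (24) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, and adjusted over all lists. The lists covered the cell cycle, pocket proteins and kinases, DNA methylation, chromatin, surface targets, checkpoint ligands, androgen-regulated genes, luminal, neuroendocrine and basal states, interferon, antigen presentation, germline genes, p53, hypoxia, sterols, stress, immediate early genes, RB1 neighbors and 4 kinds of host cells. The biological coefficient of variation was 15.2%.

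Lists, tests and the naming rule were fixed before the data were examined. The rule named RB1, CD276, each DNA methylation gene past the test, the 10 largest rises and 10 largest falls among protein coding genes past the test with a mean log2 CPM of at least 1 and groups that did not overlap, up to 4 members of each other list with the smallest p, and a set of cell cycle and prostate genes wherever tested. Some genes that the rule names are not reported here. Fold changes with 0 counts in a group are given against 3 counts over the group, and those with 1 to 3 counts as ratios with 95% exact intervals.

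Windows of 50 neighboring genes were compared with random gene sets and chromosomes with 10000 block permutations. The plan named 10000 random sets for windows; 100000 were used, since on simulated data 10000 could not pass the adjustment over 274 windows. On data simulated for this comparison, with 14475 genes tested, the edgeR test called 30% of genes changed 1.5-fold, 82% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, and 10 of 14235 unchanged genes. Camera found the shifted list and 0 of 20 random lists. Besides the shifted list, 50 genes were changed at each fold, a far smaller share than the 49.2% of tested genes called in the data. The recovered shares can therefore differ from those of the real test. The simulated genes varied independently and no library was made to stand apart. The simulation therefore cannot tell how camera behaves on genes that vary together.

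Alternatives were RLE, upper quartile and library size scaling, DESeq2 1.42.0, limma-voom, 3 other count filters, the replicate number as a block, each library left out, and for lists an estimated correlation and fry. Chosen after the data were seen were the removal of each library's smooth trend with transcript length and GC content (mgcv 1.9.3, basis size 40), an estimated correlation without control replicate 3, and the gene families in the closing section. Values of length and GC were available for 99.2% of tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.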

Results

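RNA was sequenced from 22Rv1 xenografts, tumors grown under the skin from a human prostate carcinoma cell line. The design compared 3 control tumors, whose cells carried a guide RNA against GFP, with 3 tumors whose cells carried a guide RNA against RB1, the retinoblastoma tumor suppressor that restrains E2F transcription factors. The labels name the 3 libraries of each group xenograft replicates and do not say whether they came from separate animals, so the p-values measure the spread between these samples. Library totals were 11278823, 11957569 and 15883900 counts in control replicates 1, 2 and 3, and 12569452, 12594215 and 12896688 in the RB1 knockout replicates. Of 32555 genes in the table, 14416 had enough counts to be tested. The groups separated along the first principal component, which held 75.4% of the variance. Control replicate 3 stood apart from the other 2 controls along the second, which held 15.6%. Genes with a symbol of RPL or RPS and a digit, mostly ribosomal proteins, took 15.3% of its counts. They took 9.76% and 10.1% in control replicates 1 and 2, and 6.49%, 6.97% and 6.57% in the knockout libraries. This set leaves out RPLP0, RPLP1 and RPLP2 and takes in RPS6K kinase genes.

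The targeted gene was lower in every library labelled knockout than in every control library. RB1 (ENSG00000139687, chromosome 13 from 48303726 to 48599436 in GRCh38) measured 20.4, 21.5 and 19.7 CPM (counts scaled to a common library size) in the controls and 9.41, 9.36 and 9.25 CPM in the knockouts. The group means were 20.5 ± 0.90 (SD, n = 3) and 9.34 ± 0.081 CPM (SD, n = 3). The log2 fold change was -1.14 (SE 0.11), with an adjusted p of 1.42e-04 in edgeR's quasi-likelihood test. The transcript was therefore 2.20-fold lower and still present, with 372 counts in the 3 knockout libraries together. Gene counts do not show whether the remaining transcript carries an edit. Among 12 tested genes that neighbor RB1, 4 rose, 2 fell and 6 did not pass the test. Leaving out control replicate 1, 2 or 3 gave 1, 2 and 7 higher, with 2 lower each; leaving out knockout replicate 1 gave 1 higher and 2 lower, and leaving out knockout replicate 3 gave 1 of each. After removal of a transcript length and GC trend, chosen after the data were seen, 2 rose and 2 fell. RCBTB2 changed by 0.88 (SE 0.17, edgeR adjusted p = 0.00379) and ESD by -0.59 (SE 0.14, edgeR adjusted p = 0.010) on the log2 scale. The list as a whole did not pass camera, with an adjusted p of 0.463.

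**Figure D1:**
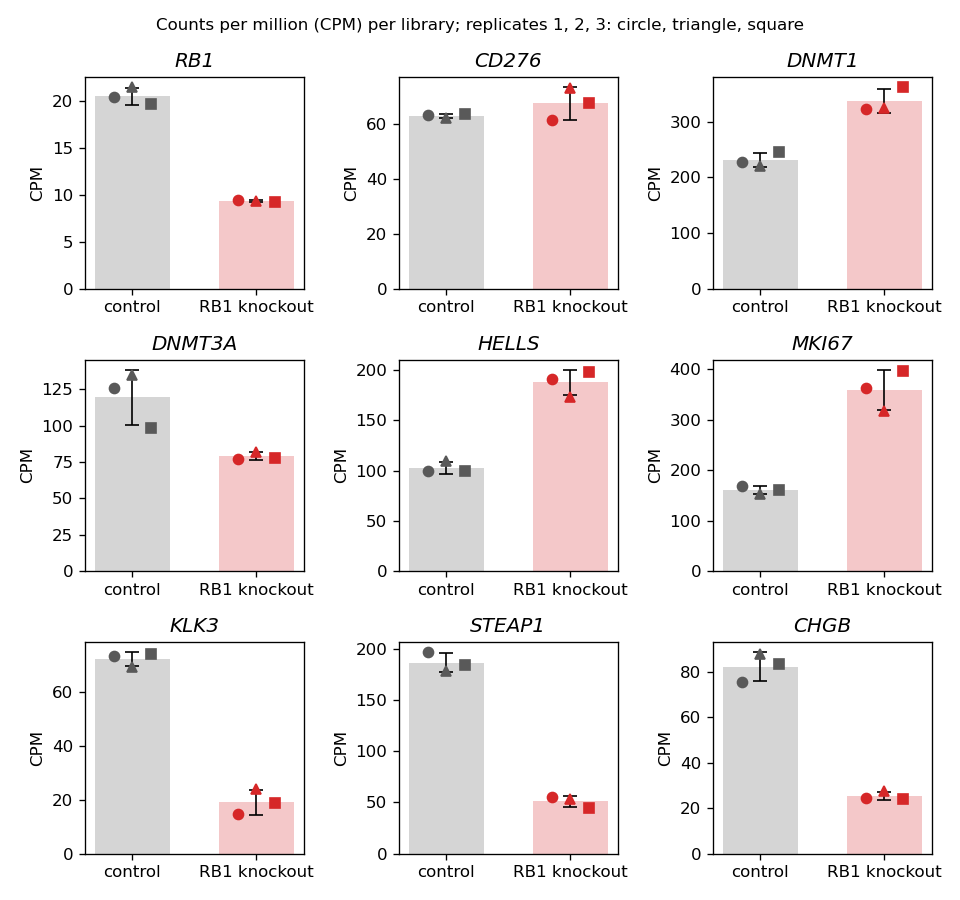
CPM (vertical axes) of 9 genes in the control and RB1 knockout libraries. Bars are means of 3 libraries, error bars are 1 SD, and symbols mark replicates 1, 2 and 3 (circle, triangle, square). RB1 averaged 20.5 CPM in the controls and 9.34 CPM in the knockouts, and the CD276 values of the groups overlapped.

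The transcriptome differed widely between the groups. In the knockout tumors 3685 genes were higher and 3414 were lower at an adjusted p under 0.05 in edgeR's quasi-likelihood test, together 49.2% of the genes tested. A change of at least 2-fold was found for 1091 higher and 1177 lower genes, and 117 rose and 103 fell by at least 8-fold. For 61.8% of tested genes all 3 knockout libraries lay on 1 side of all 3 controls, where chance gives 10%. With library size as the only scaling, 4459 genes were higher and 2463 lower, so the higher share of the calls moved from 51.9% to 64.4%; this scaling shifted the median log2 fold change of all genes by 0.13. Without control replicate 3 the test called 4844 higher and 4624 lower genes.

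Genes that were nearly silent in the controls included some of the largest rises. MS4A15 had 0 counts in the 3 controls and 153 in the knockouts, which is at least 47.4-fold higher when the control group is set at 3 counts. SMCO1 went from 1 count to 313, a ratio of 291 (95% counting interval 51.8 to 11518), and MAEL, a germline gene of the piRNA pathway, from 2 counts to 211, a ratio of 98.0 (95% counting interval 26.8 to 814). These limits and intervals cover counting error only. GLDN, which encodes gliomedin, rose from 0.578 ± 0.140 to 106 ± 1.18 CPM (SD, n = 3 each), a log2 fold change of 7.52 (SE 0.15, edgeR adjusted p = 5.11e-07). FMOD, the collagen-binding proteoglycan fibromodulin, rose from 2.33 ± 0.894 to 292 ± 12.6 CPM (SD, n = 3 each). FYN, a Src family tyrosine kinase, rose from 9.92 ± 1.84 to 500.1 ± 12.9 CPM (SD, n = 3 each), a log2 fold change of 5.65 (SE 0.15, edgeR adjusted p = 1.38e-06). The remaining rises named by size were GDF7 at 5.98, CAPN9 at 5.70, B4GALNT2 at 5.26 and CEACAM6 at 5.13 on the log2 scale.

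The largest falls included abundant transcripts. C1QL4 dropped from 2443 ± 535 to 11.4 ± 6.41 CPM (SD, n = 3 each), a log2 fold change of -7.75 (SE 0.44, edgeR adjusted p = 2.00e-05). BEX1 fell from 107 ± 51.9 to 0.777 ± 0.212 CPM and CFC1, an EGF-CFC family member, from 186 ± 29.9 to 2.34 ± 0.494 CPM (SD, n = 3 each). GATA3, a transcription factor of luminal epithelia, changed by -5.98 (SE 0.67, edgeR adjusted p = 3.17e-04). The log2 fold changes of CLSTN2, ADAM7, CPS1 and RGS5 were -7.38, -6.76, -6.56 and -6.29. TCEAL5 had 175 counts in the controls and 3 in the knockouts, a ratio of 62.8 (95% counting interval 21.1 to 308). TF, which encodes transferrin, had a log2 fold change of -5.90 (SE 1.80, edgeR adjusted p = 0.0269), and it rested on 1 library, since control replicate 3 measured 61.1 CPM and control replicates 1 and 2 measured 1.24 and 1.78 CPM. Without that library the log2 fold change of TF was -2.08. The call of TF was lost with limma-voom (adjusted p = 0.216) and without knockout replicate 1, 2 or 3 (edgeR adjusted p of 0.0982, 0.0828 and 0.0889). CPS1 was likewise highest in control replicate 3, at 26.5 CPM against 5.87 and 5.50 CPM.

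The series title names DNA methylation and B7-H3, the product of CD276, as targets in prostate cancer. Of 24 tested genes that write, erase or read DNA methylation or support these steps, including metabolic enzymes, 9 rose, 3 fell and 12 did not pass the test, and adjustment over the list alone gave the same 9 and 3. DNMT1, the maintenance methyltransferase, rose from 232 ± 12.4 to 337 ± 21.8 CPM (SD, n = 3 each), a log2 fold change of 0.54 (SE 0.09, edgeR adjusted p = 0.00201). HELLS, a chromatin remodeler needed for DNA methylation, rose by 0.87 (SE 0.09, edgeR adjusted p = 2.52e-04). DNMT3A, a de novo methyltransferase, fell from 120 ± 18.9 to 79.2 ± 2.44 CPM (SD, n = 3 each), a log2 fold change of -0.60 (SE 0.12, edgeR adjusted p = 0.00558). The other rises were the metabolic enzymes IDH1 (0.84), IDH2 (1.02) and MAT2A (0.56), as well as the methyl-CpG readers MBD2 (0.35), ZBTB33 (1.28), ZBTB38 (0.93) and ZBTB4 (0.23), and the other falls were MBD3 (-0.27) and GADD45G (-0.57). The call of MBD2 was lost after removal of the length and GC trend, and that of GADD45G with the trend removed and without any 1 knockout library. Those of MBD3 and ZBTB4 were lost without any 1 library other than control replicate 3 and under other settings. As a list these genes did not differ from the rest by camera (adjusted p = 0.361). Without control replicate 3, 10 rose and 6 fell, and without any 1 knockout library 8 rose and 1 fell.

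CD276 did not differ beyond the spread between replicates. It measured 62.9 ± 0.773 CPM in the controls and 67.3 ± 5.88 CPM in the knockouts (SD, n = 3 each), with a log2 fold change of 0.10 (SE 0.09) and an edgeR adjusted p of 0.391. After removal of the length and GC trend its log2 fold change was 0.31 with an edgeR adjusted p of 0.00882. Among 10 tested B7 family and checkpoint ligands, 3 rose, 2 fell and 5 did not pass. With 3 still higher, 1 fell without control replicate 1 or 2 and 0 fell without knockout replicate 1 or 3. VTCN1, the B7-H4 gene, rose from 0.406 ± 0.168 to 14.1 ± 0.761 CPM (SD, n = 3 each), a log2 fold change of 5.09 (SE 0.25, edgeR adjusted p = 1.09e-05). ICOSLG and NCR3LG1 rose by 1.23 and 0.90, and PVR changed by -0.38 (edgeR adjusted p = 0.0137). The call of PVR was lost with library size as the only scaling (edgeR adjusted p = 0.0541) and without knockout replicate 1 (0.0699) or 3 (0.0501). Of 20 tested surface proteins used as therapy targets in prostate cancer, 9 rose, 4 fell and 7 did not pass. STEAP1 fell from 187 ± 9.35 to 51.0 ± 5.55 CPM (SD, n = 3 each), while ALCAM rose by 1.59 and ERBB3 by 1.12 on the log2 scale. FOLH1, which encodes PSMA, measured 703 ± 48.3 and 666 ± 44.5 CPM (SD, n = 3 each; edgeR adjusted p = 0.538). Neither list passed camera, with adjusted p of 0.561 for the checkpoint ligands and 0.478 for the surface targets.

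Genes of the cell cycle rose together. Of 50 genes of the G1/S transition and DNA replication, 41 rose, 0 fell and 9 did not pass, or 43 higher when adjusted over the list alone; their median log2 fold change was 0.70. Camera gave an adjusted p of 9.57e-10 with a preset correlation. With an estimated correlation, under which 0 of the 24 lists passed, the adjusted p was 0.841. MCM6 and MCM4, subunits of the replicative helicase, rose by 1.65 (SE 0.11, edgeR adjusted p = 4.29e-05) and 1.44 (SE 0.10, edgeR adjusted p = 4.44e-05). CLSPN rose by 1.56, SLBP by 1.24 and CCNE2 by 1.10. Of 42 genes of G2 and mitosis, 26 rose, 3 fell and 13 did not pass, with 27 and 3 when adjusted over the list alone; camera gave an adjusted p of 5.29e-05, and the adjusted p was 0.841 with an estimated correlation. ANLN rose by 1.59, DLGAP5 by 1.43, ECT2 by 1.34 and MAD2L1 by 1.21. MKI67, a marker of cycling cells, rose from 161 ± 8.65 to 359 ± 40.03 CPM (SD, n = 3 each; edgeR adjusted p = 1.33e-04).

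A further list held pocket proteins, cyclin-dependent kinases, D cyclins, inhibitors, E2F3 to E2F6, TFDP1, TFDP2 and SKP2. Of its 22 tested genes, 14 rose, 1 fell and 7 did not pass, with 15 and 2 when adjusted over the list alone. Camera gave an adjusted p of 0.0168, and the adjusted p was 0.808 with an estimated correlation. The rises included the RB1 relative RBL1 (1.06) and the kinase CDK4 (0.72) as well as inhibitors of these kinases, CDKN2B (1.68), CDKN2C (1.17) and CDKN1A (0.67). The call of CDKN1A was lost without knockout replicate 2 (log2 fold change 0.59, edgeR adjusted p = 0.0543). CDK6 rose by 1.005 (SE 0.24, edgeR adjusted p = 0.0108), a call that was lost after removal of the length and GC trend (log2 fold change 0.61, edgeR adjusted p = 0.121). E2F1 measured 79.8 ± 27.5 CPM in the controls and 125 ± 1.36 CPM in the knockouts (SD, n = 3 each), a log2 fold change of 0.65 (SE 0.21, edgeR adjusted p = 0.0354), and control replicate 3 alone measured 111 CPM. Its call was lost without control replicate 1 or 2 and without any 1 knockout library. CCNE1 did not pass (log2 fold change 0.66, edgeR adjusted p = 0.131) and was 13.95 CPM in control replicate 3; without that library its log2 fold change was 1.23 with an edgeR adjusted p of 1.90e-07. E2F3 (-0.14) and CDKN2A (-0.18) did not pass; E2F3 passed with the trend removed (-0.30, edgeR adjusted p = 0.0282). Without control replicate 3, 48 of the 50 replication genes rose and 0 fell, 35 of the mitosis genes rose and 3 fell, and 16 of the pocket protein and kinase genes rose and 4 fell. Without control replicate 1, 14 of the latter rose and 2 fell, and without knockout replicate 2, 26 of the mitosis genes rose and 1 fell.

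**Figure D2:**
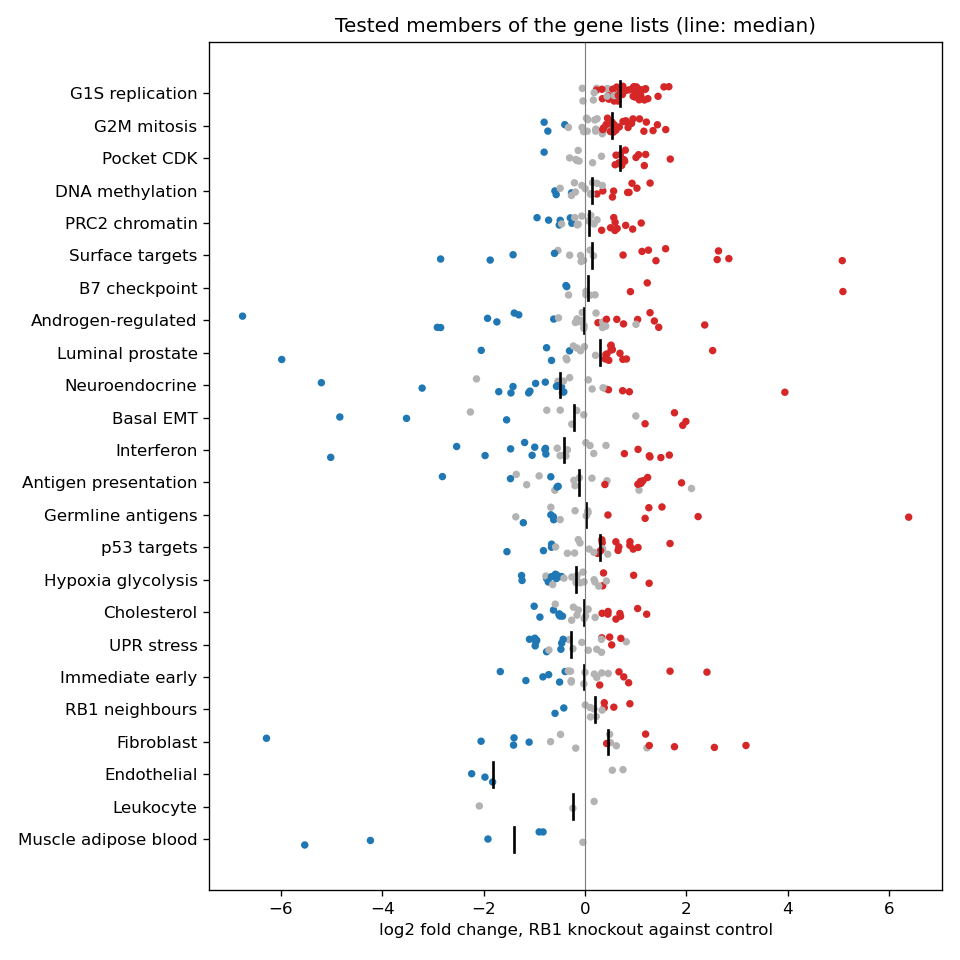
Log2 fold change of the knockout against the control group (horizontal axis) for each tested member of the 24 gene lists (rows). Red and blue points are members that rose or fell at an adjusted p under 0.05, gray points did not pass, and black lines are list medians. The replication genes have a median of 0.70 and the neuroendocrine genes a median of -0.50.

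Androgen-regulated genes went both ways. Of 30 tested, 9 rose, 8 fell and 13 did not pass. KLK4 fell from 511 ± 44.7 to 67.7 ± 10.0 CPM and KLK2 from 213 ± 16.4 to 29.5 ± 5.22 CPM (SD, n = 3 each), with log2 fold changes of -2.91 (SE 0.14, edgeR adjusted p = 9.49e-06) and -2.85 (SE 0.14, edgeR adjusted p = 1.25e-05). KLK3, the gene of prostate-specific antigen, changed by -1.92 (SE 0.16, edgeR adjusted p = 9.95e-05). RAB3B rose by 2.36. TMPRSS2 measured 139 ± 32.5 and 137 ± 12.3 CPM (SD, n = 3 each; edgeR adjusted p = 0.917); without control replicate 3 its log2 fold change was -0.20 with an edgeR adjusted p of 0.0178. Without control replicate 3, 12 of the androgen-regulated genes rose and 13 fell. Of 24 luminal prostate genes, 12 rose and 5 fell, with EHF at 2.52, DPP4 at -2.05 and CLDN3 at -0.76; without knockout replicate 1, 2 or 3, 6, 6 and 7 of them rose and 4 fell. Camera's adjusted p was 0.985 for the androgen-regulated genes, whose mean was below 0 while camera placed them higher, and 0.732 for the luminal genes, whose median was 0.30 and mean -0.09.

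Neuroendocrine genes were lower on balance. Of 26 tested, 4 rose, 13 fell and 9 did not pass, with 5 and 14 when adjusted over the list alone. CELF3, a neuronal RNA-binding protein, fell from 110 ± 10.5 to 11.9 ± 1.97 CPM (SD, n = 3 each), a log2 fold change of -3.21 (SE 0.14, edgeR adjusted p = 7.53e-06). The granule proteins CHGB and CHGA changed by -1.70 (SE 0.10, edgeR adjusted p = 2.33e-05) and -5.20 (SE 0.45, edgeR adjusted p = 1.06e-04), and PEG10 by -1.09. SYP, which encodes synaptophysin, did not pass (log2 fold change -0.45, edgeR adjusted p = 0.0568), but passed with RLE or upper quartile scaling (edgeR adjusted p of 0.0479 and 0.0412), in DESeq2 (adjusted p = 0.0349) and without control replicate 2 or 3 (edgeR adjusted p of 0.0237 and 0.00468). Camera gave an adjusted p of 0.0443 for the list, and the adjusted p was 0.808 with an estimated correlation. Without control replicate 3 camera's adjusted p was 0.231, with 5 genes higher and 14 lower, and without knockout replicate 1 it was 0.0846, with 2 higher and 12 lower. It was 0.0511 with RLE scaling and 0.0701 with the length and GC trend removed.

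Of 25 tested Polycomb and repressive chromatin genes, 9 rose and 6 fell. Leaving out control replicate 3 gave 11 higher and 10 lower; without control replicate 2, 9 rose and 3 fell, and without any 1 knockout library 8 rose and 3 fell. CBX5 rose by 1.11 and SUZ12 by 0.94, EZH1 changed by -0.95, and EZH2 rose by 0.33 (SE 0.10, edgeR adjusted p = 0.0285), a call that was lost when any 1 library other than control replicate 3 was left out, or the length and GC trend was removed. Among 14 basal and mesenchymal genes 4 rose and 3 fell, including the intermediate filament gene VIM at -3.52 (SE 0.16, edgeR adjusted p = 8.35e-06), CDH2 at -1.55, LAMB3 at 1.99 and ITGB4 at 1.93. Of 15 basal and mesenchymal genes tested without control replicate 3, 8 rose and 3 fell, and the median went from -0.21 to 0.91. Of 25 interferon response genes, 6 rose (ISG20 by 1.27, USP18 by 0.78) and 10 fell (MX2 at -2.53); 5 rose and 6 fell without knockout replicate 1, and 6 of each without knockout replicate 3. Of 23 antigen presentation genes, 7 rose and 5 fell. HLA-B and HLA-C rose by 1.14 and 1.10, and HLA-DMB changed by -1.47. Without knockout replicate 1 or 3, 5 antigen presentation genes rose and 1 fell, and without knockout replicate 2, 4 rose and 2 fell. Among 17 germline genes 6 rose and 4 fell, with MAGEA1 at 1.18 and TEX15 at 1.52. Leaving out knockout replicate 1, 2 or 3 gave 6, 4 and 3 germline genes higher and 2, 0 and 1 lower. Camera's adjusted p was 0.732 for the chromatin genes, 0.985 for the basal genes, 0.571 for the interferon genes, 0.787 for antigen presentation and 0.787 for the germline genes. The antigen presentation median was -0.11, and 0.03 without control replicate 3, whereas its mean was 0.05 and camera placed it higher.

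Of 26 p53 targets, 12 rose and 4 fell, among them PPM1D at 0.95 and TP53INP1 at -1.54. Without control replicate 1, 7 of them rose and 5 fell, and leaving out knockout replicate 1, 2 or 3 gave 7, 6 and 8 higher and 3, 4 and 2 lower. Of 27 hypoxia and glycolysis genes, 4 rose and 9 fell, with the glycolytic enzyme genes GAPDH at -0.76, ALDOC at -1.24 and ALDOA at -0.56. Sterol and fatty acid genes split into 8 higher and 7 lower of 25, with CYP51A1 at 1.22 and MVD at -0.89; leaving out knockout replicate 1, 2 or 3 gave 6, 7 and 6 higher and 3, 3 and 2 lower. Among 22 stress response genes 4 rose and 9 fell, with XBP1 at 0.53, HSP90B1 at -1.10 and TRIB3 at -0.99. Among the stress genes 8 rose and 11 fell without control replicate 3, and leaving out knockout replicate 1, 2 or 3 gave 3, 3 and 4 higher and 4 lower. Of 22 immediate early genes, which also respond to tissue handling, 6 rose and 6 fell, with KLF4 at 2.40 and EGR1 at -0.83; 6 rose and 10 fell without control replicate 3, and 4 rose and 3 fell without knockout replicate 3. Camera's adjusted p was 0.361 for the p53 targets, 0.361 for hypoxia and glycolysis, 0.985 for the sterol genes, 0.571 for the stress genes and 0.985 for the immediate early genes. Hypoxia and glycolysis passed without control replicate 3 (adjusted p = 0.00637), with 5 genes higher and 19 lower, and had 2 higher and 7 lower without knockout replicate 3.

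Xenografts hold host cells, whose reads can align to human genes. Of 18 tested fibroblast genes, 6 rose and 5 fell, with COL6A1 at 1.19, DCN at -1.41, TAGLN at -2.05 and RGS5 at -6.29; their median was 0.46 and their mean -0.02 (camera adjusted p = 0.985), and the median was 0.22 without control replicate 1 and 0.13 without control replicate 2. The summed level of the fibroblast genes was 384, 379 and 441 CPM in the controls and 263, 313 and 250 CPM in the knockouts; for the endothelial genes it was 22.8, 26.5 and 28.9 against 10.4, 14.1 and 11.2 CPM. Of 5 endothelial genes, 0 rose and 3 fell, among them ENG at -1.82 and EGFL7 at -2.24 (camera adjusted p = 0.454); without control replicate 3, 1 rose and 3 fell. None of 3 leukocyte genes passed edgeR's test, with CD14 at -2.09 and an adjusted p of 0.0503 (camera adjusted p = 0.787). CD14 passed without control replicate 1 (edgeR adjusted p = 0.0281) or 2 (0.0205), with RLE or upper quartile scaling, in DESeq2 and with no count filter. Its log2 fold change ran from -2.48 to -0.68 with 1 library left out. Without control replicate 3 the leukocyte median was 0.24, with 0 of 4 past the test. Few listed host genes could be tested: 3 of 21 leukocyte, 5 of 14 endothelial and 6 of 18 muscle, fat and blood genes in the table. Leukocyte genes past the test were 1, 2 and 1, all lower, without control replicate 1, control replicate 2 or knockout replicate 1. The summed level of the leukocyte genes was 23.8, 22.6 and 57.9 CPM in the controls and 23.1, 22.6 and 26.1 CPM in the knockouts. Of 6 muscle, fat and blood genes, 0 rose and 5 fell. Leaving out control replicate 3 gave 2 higher and 5 lower of 7, and without control replicate 1, control replicate 2 or knockout replicate 3, 1 of 7 rose and 5 fell. Camera gave an adjusted p of 0.0179, and the adjusted p was 0.808 with an estimated correlation, 0.219 without control replicate 3, 0.226 without knockout replicate 3, 0.115 with no count filter and 0.0625 with the length and GC trend removed. The hemoglobin genes HBA2 and HBA1 changed by -5.53 and -4.23, and HBA2 was 168 CPM in control replicate 3. The summed level of the listed muscle, fat and blood genes was 129, 140 and 338 CPM in control replicates 1, 2 and 3, and 99.5, 110 and 96.1 CPM in the knockouts.

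Neighboring genes were compared for shared shifts. Of 274 windows of 50 neighboring tested genes, 38 had a median log2 fold change beyond 100000 random sets of 50 genes at an adjusted p under 0.05, of which 21 were higher and 17 lower. Chromosomes 4 (0.20 above all genes), 16 (-0.14) and 19 (-0.26) passed a permutation test of blocks of genes, with adjusted p of 0.0115, 0.0337 and 0.00230. Among genes with a mean count of at least 50 chromosome 16 no longer passed (-0.14, adjusted p = 0.0820). After removal of the length and GC trend, 1 window and chromosome 19 passed, with chromosome 19 at -0.10 against -0.26 before. That window lies on chromosome 19 from 49906825 to 52139922 in GRCh38, between NUP62 and ZNF616, and holds the kallikrein genes; its median lay at -0.62 relative to all genes before and at -0.47 after the correction.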

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

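Tests with the length and GC trend removed, the estimated correlation without control replicate 3, and list counts with 1 library left out were chosen after the data were seen. Counts of changed genes stayed within 1.5 times the reported ones under all 16 alternatives: 2807 to 4844 higher, 2299 to 4624 lower, 734 to 1420 at least 2-fold higher and 803 to 1308 at least 2-fold lower. Of the alternatives, RB1 stayed lower and past the test in each, from -1.37 to -1.004 on the log2 scale. CD276 stayed above 0, from 0.042 to 0.31, and passed only with the length and GC trend removed, at 0.31 (adjusted p from 0.00882 to 0.751 over its alternatives); the cause was not tested. Named genes kept their direction and side of the threshold in 2045 comparisons with an alternative, lost the call in 49, gained it in 21 and changed sign in 12. Each gene that changed sign had not passed the reported test: TMPRSS2 was 0.094 with library size only, 0.0027 with limma-voom and -0.20 to 0.13 with 1 library left out, FOLH1 was 0.059 with library size only, CDKN2A was 0.29 with the trend removed and -0.31 to 0.087 with 1 library left out, LCP1 was -0.36 to 0.013 and CD68 was -0.14 to 0.70 with 1 library left out. The cause was not tested. The same-numbered libraries showed no shared deviation (correlations 0.083, -0.063 and -0.0015). Control replicate 3 dominated the deviations of the controls, so a smaller effect shared by number could be missed. Pairing by replicate number is therefore not excluded. With the replicate block 3471 genes were higher and 3114 lower, and knockout replicate 1 correlated best with control replicate 1, but the other knockout libraries did not correlate best with their own number.

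The number of lists past the test was 5 as reported, 0 with an estimated correlation, with or without control replicate 3, 9 with directional fry, 23 with mixed fry and 3 with the length and GC trend removed. Of the host lists, 1 passed as reported, 0 with an estimated correlation, with the trend removed and with no count filter, 2 with directional fry, 3 with mixed fry and 0 to 1 with 1 library left out. With an estimated correlation, camera's adjusted p was 0.841 for replication, 0.841 for mitosis, 0.808 for pocket proteins and kinases and 0.808 for neuroendocrine genes. Without control replicate 3 it was 0.702 for each of these. In all libraries the estimated correlations were 0.62, 0.44, 0.091 and 0.038 in that order, against the preset 0.01. Over all 24 lists camera's adjusted p with an estimated correlation ran from 0.808 to 0.988, so this setting set no list apart. It cannot show which list calls rest on genes that vary together. How much of the change in p came from the estimated correlations was not tested. The neuroendocrine list had an adjusted p of 0.051 with RLE factors, 0.0519 with the replicate block, 0.0701 with the trend removed and 0.0214 to 0.231 with 1 library left out. Hypoxia and glycolysis ran from 0.00637 to 0.619 with 1 library left out.

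Fry asks whether a list's genes move, not whether they differ from other genes. Since 49.2% of all tested genes passed edgeR's test, almost any list could pass mixed fry, and 23 of 24 did. Such a pass therefore does not set a list apart from the other genes. Fry's directional adjusted p was 0.00807 for DNA methylation, 0.0106 for surface targets and 0.00684 for checkpoint ligands. Its mixed adjusted p was 1.30e-06 for DNA methylation, 2.49e-05 for chromatin, 3.23e-06 for surface targets, 8.13e-06 for checkpoint ligands, 1.53e-06 for androgen-regulated genes, 6.65e-05 for luminal, 3.57e-06 for basal, 5.38e-07 for interferon, 9.19e-06 for antigen presentation, 1.49e-05 for germline, 3.57e-06 for p53, 3.46e-04 for hypoxia, 7.41e-05 for sterol, 1.60e-04 for stress, 1.13e-06 for immediate early and 7.41e-05 for RB1 neighbor genes.

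Lists that changed sign had not passed the reported test, and the cause was not tested. Androgen-regulated genes turned with the trend removed (0.780), library size only (0.948), directional fry (0.531), and an estimated correlation without control replicate 3 (0.985), and had 0.930 to 0.990 with 1 library left out. Basal genes turned with the trend removed (0.814), directional fry (0.884), no count filter (0.793), RLE factors (0.982), the replicate block (0.975) and an estimated correlation without control replicate 3 (0.702), and had 0.557 to 0.987 with 1 library left out. Immediate early genes turned with the trend removed (0.5003), directional fry (0.381), no count filter (0.894) and the replicate block (0.975), and had 0.939 to 0.990 with 1 library left out. Germline genes turned with no count filter (0.793) and had 0.557 to 0.993, and sterol genes turned with no count filter (0.944) and had 0.665 to 0.990, with 1 library left out. Windows past the position test were 38 as reported, 44 of 223 for genes with a mean count of at least 50, and 1 with the length and GC trend removed. Depth limits genes near the filter: 3 counts are 0.189 to 0.266 CPM in these libraries.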

Other observations

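The gene families in this part and in the next paragraph, the length and GC tests of control replicate 3 and of neighboring genes, the spread and summed levels of host genes, and the use of corrected windows to weigh copy number were chosen after the values were seen. All 8 tested kallikrein genes, which lie side by side on chromosome 19, fell in the knockout tumors by edgeR, with a median log2 fold change of -2.05. Besides KLK2, KLK3 and KLK4 they were KLK1 (-1.77), KLK11 (-2.49), KLK13 (-0.89), KLK14 (-1.18) and KLK15 (-2.18). They were lower under RLE, upper quartile and library size scaling. After removal of the length and GC trend 6 of 8 passed and all 8 stayed lower, with a median of -1.88. Other androgen-regulated genes rose, including FKBP5 by 1.45 and PMEPA1 by 1.28. Of 4 tested CEACAM genes, 3 rose: CEACAM6, CEACAM5 from 3.18 ± 4.28 to 106 ± 11.5 CPM (SD, n = 3 each; edgeR adjusted p = 7.56e-04) and CEACAM19 by 1.15. CEACAM1 changed by -0.58 (edgeR adjusted p = 0.0507), and it passed under RLE and upper quartile scaling.

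Of 83 tested genes picked by a ribosomal protein symbol, 71 fell and 0 rose by edgeR, with a median log2 fold change of -1.04. The symbol rule also took in RPS19BP1, which is named as a binding protein and did not pass. Their median was -1.05 with RLE scaling, -1.04 with upper quartile scaling, -0.87 with library size scaling and -0.91 after removal of the length and GC trend. Without control replicate 3, where the similar set described with the libraries took its largest share of counts, 75 of 84 fell, 3 rose and the median was -0.68. Leaving out knockout replicate 1, 2 or 3 gave 44, 51 and 46 lower of 84 and 0 higher. Genes of mitochondrial ribosomal proteins had 3 higher and 23 lower of 74, with a median of -0.47, and 14 higher and 34 lower with a median of -0.15 without control replicate 3. The median was -0.27 after removal of the length and GC trend and -0.31 with library size scaling. Leaving out knockout replicate 1, 2 or 3 gave 9, 11 and 10 lower and 1 higher each. There were 1 higher and 34 lower without control replicate 1, and 8 higher and 19 lower with library size scaling.

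The real split of the libraries gave 7099 genes past edgeR's test and 2268 of at least 2-fold. The highest of the other splits gave 0 of each; across the other 9 splits 31 to 280 genes had an unadjusted p under 0.05. With 10 splits, of which 1 gave as many genes, a share under 0.05 cannot be reached. For gene lists, 4 of the 10 splits gave at least the 5 lists of the real split, and the highest gave 10, with control replicates 1 and 2 and knockout replicate 3 against the rest. Camera with a preset correlation thus called as many lists when control replicate 3 was set among the knockouts.

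The 7099 genes that differed between the groups were weighed against technical explanations. Length and GC content accounted for 6.34% of the variance of the fold changes, and 6980 genes passed after that trend was removed. Of these, 5672 were among the 7099 with the same direction and 1 with the opposite direction, so the trend is not the whole difference, although calls were lost and others gained. More host cells in 1 group would move all 4 host lists one way by at least 1. Their medians ran from -1.82 for endothelial to 0.46 for fibroblast genes, which met the bound set beforehand against this explanation, namely that the medians differ in sign. A condition added after the values were seen, that a median must lie beyond the SD of its members, was not met by the fibroblast genes (SD 2.10), 6 of which rose and 5 fell. The summed levels were lower in every knockout library than in every control for fibroblast, endothelial and muscle, fat and blood genes, and overlapped between the groups for leukocyte genes. These lower sums would go with more host reads in the controls. Host reads added to the controls would not raise genes in the knockouts. The 1091 genes at least 2-fold higher in the knockouts therefore argue against host reads as the whole difference. For the other changed genes, more host cells in 1 group stay open, neither shown nor excluded. The RB1 guide stays open as an explanation, as does any other difference between the 2 cell populations, which the design does not separate from the guide.

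Control replicate 3 differed from the other controls. Length and GC content accounted for 8.23% of the variance of its difference, against 0.18% between control replicates 1 and 2. They also accounted for 6.14% for knockout replicate 1 against the other knockouts, so such a trend was not particular to control replicate 3. The 8.23% lies between the bounds set for a main cause and for none. In control replicate 3, host genes had median log2 differences of 0.67 for endothelial (3 of 5 higher) and 1.06 for leukocyte genes (all 3). The median was 0.69 for muscle, fat and blood genes (4 of 6 higher). It was smallest, 0.29, for fibroblast genes (12 of 18 higher), just under the bound of 0.3 that all lists had to exceed. More host cells in that tumor may contribute, and neither this nor the trend can be told apart from a tumor that differed in other ways, because it is a single library and no biological explanation was tested.

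Neighboring genes changed together in 13.9% of windows, which met the bound of 10% set beforehand for copy number differences between the cell populations. The difference of control replicate 3 from the other controls gave 5 windows past the test against 38, so that difference did not give as many. Its rank correlation was 0.18 with GC content and -0.37 with transcript length, against -0.29 and 0.25 between the groups. Control replicate 3 is itself one of the controls, so the opposite signs do not exclude that it adds to the trend between the groups. Differences between knockout libraries were not compared in windows, so other library differences are not excluded. After removal of the length and GC trend 1 window stayed, which is what a trend along regions of similar base content would give. The 38 windows had a median absolute shift of 0.37. After the correction some windows fell just short, as on chromosomes 1 (0.33) and 12 (-0.34), with an adjusted p of 0.0690 against random sets. The count of windows thus does not show how much of each shift went. The trend test was chosen after the corrected windows were seen. The correction could also remove part of a true copy number signal, so copy number stays open and needs DNA data. The window that stayed holds the kallikrein genes, whose falls were unequal. Their log2 fold changes ran from -0.89 for KLK13 to -2.91 (SE 0.14) for KLK4, with KLK3 at -1.92 (SE 0.16). A single copy number change alone would move neighbors alike, so these values argue against it as the whole cause of the kallikrein falls. It may still add a part, which the counts do not separate from local regulation.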
